A study of Mus musculus with 30 samples.

How the data were processed

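The series measured m6A with antibody-based sequencing in 30 libraries of mouse embryonic stem cells, 15 inputs and 15 immunoprecipitates, in 8 groups set by vector (EV or rat L2HGDH cDNA), treatment (untreated, or 500 nM myxothiazol for 16 hours) and fraction. Untreated EV cells had 3 libraries of each fraction and the other conditions 4. The submitters' processing notes name STAR, DESeq2 and the genome build GRCm38, without versions, and the peak caller is not given in the sources used here.

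The authors' peak lists, 1 per condition, give each peak an enrichment p-value of immunoprecipitate over input in the authors' deposited files. The log10 of this p-value and of its FDR are the authors' scores, per the file headers, and minus infinity stands where the FDR was too small to be written. The fold enrichment of a peak is the authors' ratio of read density in immunoprecipitate over input, deposited without an error. Across lists it was used for cuts at 2 and 4 and for medians, although its range differs between lists. A fold of at least 4 was reached by 67.3% of untreated L2HGDH and 16.6% of untreated EV peaks. For each treatment the authors deposited a table of differential peaks with the log2 fold change of enrichment between vectors and log10 scores of its p-value and FDR, whose lowest value is -434. The expression tables, 1 per treatment, were made by the authors with DESeq2, taken here to be on input libraries: the mean normalised count is the authors' signal, the mean of counts divided by size factors, and the log2 fold change with its standard error is the authors' deposited, unshrunken estimate. The Wald statistic is the authors' score, the log2 fold change over its standard error, and the deposited adjusted p equals the Benjamini-Hochberg adjustment over all genes of the table. Positive values mean higher in L2HGDH cells, settled from L2hgdh itself and, for peaks, from the overlap with the peak lists. No column of per-library values was used, so depth per library is unknown and precision rests on the authors' standard errors; the number of unassigned columns was 0.

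Peaks of different lists were called shared when their exon blocks overlapped by at least 1 bp on the same strand. Gene symbols were brought to current RefSeq symbols of GRCm38, and 1711 of 17670 names of the untreated expression table matched a synonym and 855 no RefSeq gene. Peak position was measured as the place of the peak middle along the RefSeq gene span, since transcript parts and the sequence motif of m6A were not analysed here. Shares have 95% Wilson intervals. The 2 differential peak tables were compared with 1 pair of overlapping peaks per gene, and signs were permuted 100000 times. The difference of the L2HGDH effect between treatments was tested as the difference of the log2 fold changes over the root of the summed squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment over 16950 genes in both tables; the 2 tables share no library.

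There were 31 gene lists, fixed with the comparisons, thresholds and tests before the data were examined: m6A writers, m6A erasers and readers, hydroxyglutarate metabolism, naive pluripotency, formative and primed pluripotency, primitive endoderm, mesoderm, neuroectoderm, trophectoderm, fibroblasts, the 2-cell-like state, the integrated stress response, the mitochondrial unfolded protein response, glycolysis, hypoxia targets, mitochondrially encoded genes, nuclear genes of complex I, of complex III and of complexes IV and V, the citric acid cycle, oxoglutarate-dependent dioxygenases, germline genes silenced by DNA methylation, imprinted genes, p53 targets, cholesterol synthesis, interferon response, proliferation, nucleotide and aspartate synthesis, immediate early genes, antioxidant genes and cytosolic ribosomal proteins. Lists with at least 5 measured genes were tested on the Wald statistic with cameraPR of limma 3.58.1 (R 4.3.3) at a preset correlation of 0.01, with adjustment over 62 tests. The same test on genes with a peak compared genes with higher, lower or both kinds of differential peak with the rest. Over-representation of lists among genes with a differential peak was tested with one-sided Fisher's exact tests among genes with a peak in either condition of the treatment.

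Named genes followed a rule: L2hgdh; per comparison and direction the 10 genes with the largest log2 fold change at an adjusted p under 0.05 and a mean normalised count of at least 100, without predicted genes, pseudogenes and clone names; up to 4 genes per list with the smallest adjusted p, past the threshold or not for the m6A and hydroxyglutarate lists; for the difference the 5 genes per direction with the smallest adjusted p; for peaks the 10 genes per direction with the smallest FDR, ties by absolute log2 fold change, which decided among the 133 untreated and 157 myxothiazol peaks at the lowest FDR, and up to 4 per list in the same order. For the peak lists of single conditions they were members of the naive pluripotency, m6A writer and m6A eraser and reader lists.

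The alternatives tried were fold enrichment of at least 2 or 4, a peak FDR of 1e-05, merging of peaks under 100 bp apart, genes in place of peaks, overlaps of 50%, a log2 fold change of at least 1, an adjusted p of 0.01, mean counts of at least 10 or 100, preset correlations of 0 and 0.05, the log2 fold change as the list statistic and other backgrounds. Added after the data had been seen were the position in the gene span, the list test of the difference and the removal of the trend over gene span (locally weighted regression with a share of 0.3). Tested on simulated data of 16950 genes, the test of the difference of L2HGDH effects recovered 81 of 100 genes with a difference of 1 and 100 of 100 with a difference of 2 on the log2 scale, and called 9 of 16750 unchanged genes. On simulated data of 17000 genes the list test called 10 of 10 shifted and 0 of 100 unshifted lists, and 4018 overlapping peak pairs were the same as those of bedtools 2.31.1. Simulated genes were independent, and noise for the difference was drawn from the standard errors used in its test. The simulations thus say nothing about correlated genes or a trend over gene span. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.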

Results

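Poly(A) RNA of mouse embryonic stem cells was sequenced directly (input) and after immunoprecipitation with an antibody against m6A, the methyl mark on adenosines inside mRNA. The cells carried an empty vector (EV) or a rat cDNA of L2HGDH, the mitochondrial enzyme that oxidises L-2-hydroxyglutarate to 2-oxoglutarate, and were left untreated or given 500 nM myxothiazol, an inhibitor of respiratory complex III, for 16 hours. The 30 libraries made 8 groups, with 3 input and 3 immunoprecipitated libraries for untreated EV cells and 4 libraries in each of the other 6 groups. The series title names mitochondrial L-2-hydroxyglutarate as a signalling metabolite, so comparing L2HGDH with EV cells asks which m6A marks and mRNA levels differ when cells carry more of the enzyme that removes this metabolite. The same comparison under myxothiazol asks this with the respiratory chain blocked. The values used here describe whole conditions and comparisons, so the depth of each library is unknown. The labels name replicates without saying that they came from separate cultures, and they give no batch. The p-values for the expression of single genes thus measure the spread between these samples, which may be technical. List, over-representation and permutation tests measure spread across genes. Whether the authors' peak FDR includes spread between libraries is not known here.

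Transcripts of the pluripotency network carried m6A peaks in EV and in L2HGDH cells. Of the 25 genes fixed as naive pluripotency markers, 15 had a peak in all 4 conditions, among them Sox2, Nanog, Klf4 and Esrrb, transcription factors of this network. Klf4, for example, had 4 peaks in untreated EV cells, 4 in untreated L2HGDH cells, 5 in EV cells with myxothiazol and 4 in L2HGDH cells with myxothiazol. Peaks on Nr5a2, Prdm14, Fbxo15 and Dppa2 were listed in both EV conditions and in neither L2HGDH condition, whereas Dppa5a had a peak in 0 of the conditions. In all, 23 of the 25 genes had a peak in untreated EV cells and 17 in untreated L2HGDH cells, and the same numbers, 23 and 17, were found with myxothiazol. Over all genes, the number with a listed peak in L2HGDH cells was 0.925 times that in EV cells without and 0.646 times with myxothiazol. The lower number with myxothiazol was thus not particular to these genes. Of the 9 genes of the m6A writer list, 7 had a peak in untreated EV cells, 6 in untreated L2HGDH cells, 9 in EV cells with myxothiazol and 5 in L2HGDH cells with myxothiazol. Mettl3, the catalytic subunit of the writer complex, had a listed peak only in EV cells with myxothiazol, and Wtap only in the EV conditions. Among the 13 m6A erasers and readers, 11, 12, 11 and 10 had a peak in the same order of conditions, with Fto, an eraser, listed only in the L2HGDH conditions and Ythdc2 in 0 of them.

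The authors' lists held 9365 peaks on 5404 genes in untreated EV cells, 8919 peaks on 4997 genes in untreated L2HGDH cells, 16036 peaks on 7325 genes in EV cells with myxothiazol and 8256 peaks on 4733 genes in L2HGDH cells with myxothiazol. Peaks covered 2049 kb, 2039 kb, 3766 kb and 1904 kb of exon in the same order. EV cells thus had 1.71 times as many listed peaks with myxothiazol as without, and L2HGDH cells 0.926 times as many. With myxothiazol the L2HGDH list had 0.515 times the peaks of the EV list. In untreated cells this ratio was 0.952, but its direction turned with the authors' fold enrichment over input, which was 1.09 at a fold of at least 2 and 3.87 at a fold of at least 4. The lists used here hold no values per library, so peak numbers were not tested between conditions, and a peak missing from a list is not a missing modification because listing depends on depth, expression and the number of libraries.

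**Figure D1:**
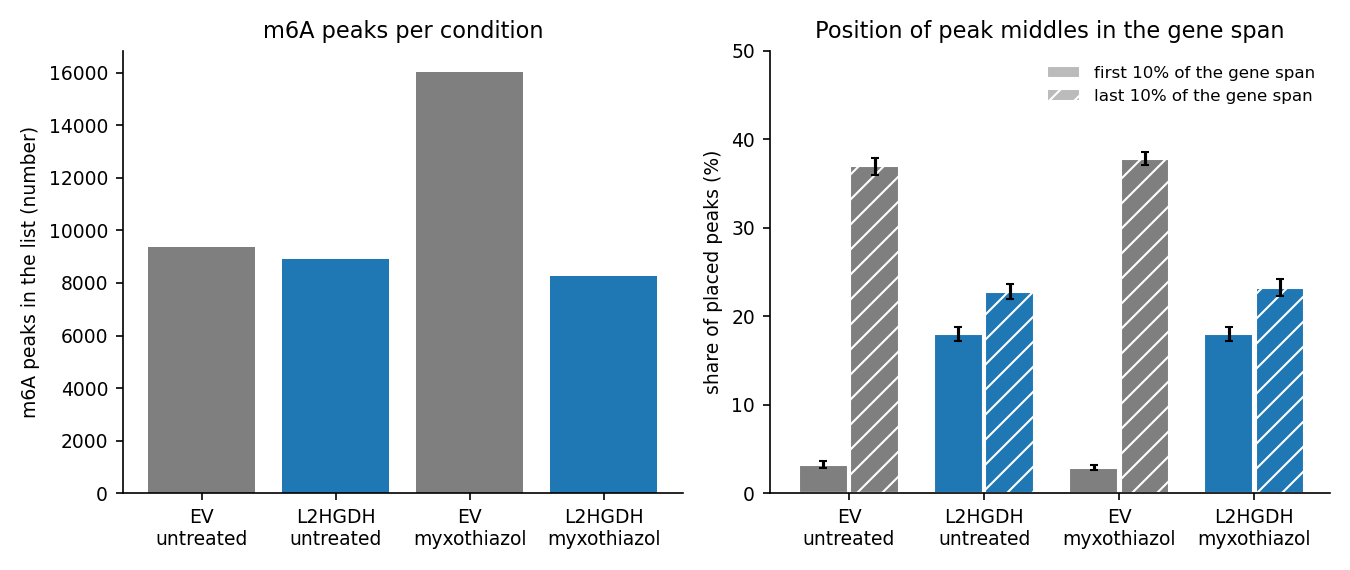
The left panel shows the number of m6A peaks in the authors' list of each condition, and the right panel the share (%) of placed peaks whose middle lies in the first or the last 10% of the gene span, with 95% Wilson intervals as error bars. The EV list with myxothiazol is the longest, at 16036 peaks, and both L2HGDH lists have 18.0% of their peaks in the first 10% of the gene.

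Peaks followed the vector more than the treatment. Of the EV untreated peaks, 87.4% overlapped a peak of EV cells with myxothiazol, and 85.1% of the L2HGDH peaks with myxothiazol overlapped a peak of untreated L2HGDH cells. In the longer list of each pair, 48.9% of EV peaks with myxothiazol and 78.3% of untreated L2HGDH peaks were shared. Across vectors, 42.5% of the untreated L2HGDH peaks overlapped an untreated EV peak, and 49.1% of the L2HGDH peaks with myxothiazol overlapped an EV peak of the same treatment. Of the longer EV lists, 40.6% without and 25.1% with myxothiazol overlapped an L2HGDH peak of the same treatment. The remaining pairs gave 43.3% for L2HGDH with myxothiazol against untreated EV and 48.7% for untreated L2HGDH against EV with myxothiazol. A set of 2960 untreated EV peaks overlapped a peak in every other list, and 2904 of the 8732 genes with any peak had one in all 4 conditions, while 1451 genes had one only in EV cells with myxothiazol. At a fold enrichment of at least 4 the overlap between untreated L2HGDH and EV peaks dropped to 3.66% of the L2HGDH list and was 13.5% of the EV list, then the shorter one, and when genes with a peak were compared in place of peaks it was 68.1%.

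The lists also differed in where the peaks lay along the gene. In EV cells 3.22% of untreated peaks (95% Wilson interval 2.88 to 3.59) and 2.89% of peaks with myxothiazol (2.64 to 3.16) had their middle in the first 10% of the annotated gene span. In L2HGDH cells these shares were 18.0% (17.2 to 18.8) without and 18.0% (17.2 to 18.8) with myxothiazol. The last 10% of the gene span held 36.9% (35.97 to 37.92) and 37.8% (37.1 to 38.6) of EV peaks, against 22.8% (21.9 to 23.6) and 23.2% (22.3 to 24.2) of L2HGDH peaks. The intervals cover counting error only, and the gene span includes introns and stands in for transcript position, a measure chosen after the peaks had been seen.

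In untreated cells, single peaks on Fbl and on the pluripotency genes Sox2, Pou5f1 and Nr0b1 were stronger in L2HGDH than in EV cells. The authors' deposited table of differential peaks gave a log2 fold change of 5.78 (54.9-fold) for a peak on Fbl, the methyltransferase of box C/D snoRNPs, from 28169748 to 28175067 of chromosome 7. It gave 1.96 (3.89-fold) for a peak on Sox2 and 1.64 (3.12-fold) for one on Pou5f1, core pluripotency factors, and 4.33 (20.1-fold) for one on Nr0b1. Zc3h13, a subunit of the writer complex, had a peak 6.92-fold higher in the authors' deposited table, and Alkbh5, an eraser, one 11.8-fold higher. Lower in L2HGDH cells were peaks on Hspa5, the main chaperone of the endoplasmic reticulum (log2 fold change -1.30 in the authors' deposited table, 34775667 to 34776202 of chromosome 2), on Fgf4 (-1.27), on Pdia3 (-1.57) and on Hat1, a histone acetyltransferase (-1.92). These are the authors' own fold changes of enrichment, which come with an FDR and without a standard error. Input enters them, and the mRNA of Fbl was 15.0-fold, of Zc3h13 3.02-fold and of Sox2 2.40-fold lower in the authors' deposited table of expression, so a large part of these rises may come from lower input.

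The authors' deposited table held 5654 differential peaks on 3752 genes of untreated cells, 4140 of them higher and 1514 lower in L2HGDH cells. The median log2 fold change in the authors' deposited table was 1.77 (3.41-fold) for the higher and -1.45 (2.73-fold) for the lower peaks. Its header does not give the direction, which was settled from the peak lists: 2469 peaks with a positive value overlapped a peak of the L2HGDH list alone and 1 a peak of the EV list alone, whereas 1286 peaks with a negative value overlapped a peak of the EV list alone and 0 a peak of the L2HGDH list alone. The FDR of 133 peaks stood at the lowest value that the authors' deposited table holds, so the genes named first among higher peaks, from Fus (4.06) to Fbl (5.78), are those of largest fold change among these ties. The first 10% of the gene span held 18.2% (95% Wilson interval 17.1 to 19.4) of higher and 1.65% (1.12 to 2.43) of lower peaks. Counted only among peaks with a fold enrichment of at least 4, the numbers were 1529 higher and 40 lower. In the lists 67.3% of untreated L2HGDH but 16.6% of untreated EV peaks reached this fold, so the cut may not treat both directions alike. On the strongest 25% of the EV list with myxothiazol, 84 differential peaks of untreated cells were higher and 670 lower. On the strongest 25% of the L2HGDH list with myxothiazol, 1351 were higher and 3 lower.

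With myxothiazol the stronger peaks again included Fbl (log2 fold change 5.27 in the authors' deposited table), Sox2 (2.20), Pou5f1 (2.01), Esrrb (2.13) and Zc3h13 (3.37). Among 157 peaks tied at the lowest FDR of the authors' deposited table, the largest fold change was that of Phf23, 6.43 (86.2-fold), from 69995766 to 69997012 of chromosome 11. A peak on Ddit3, a transcription factor of the integrated stress response, was 3.32-fold higher in the authors' deposited table, and peaks on Slc3a2 and Shmt2 were 6.32-fold and 4.47-fold higher. Input enters these fold changes too. The mRNAs of Fbl and Ddit3 were lower in L2HGDH cells with myxothiazol, so a large part of the rises of their peaks may come from lower input. Lower peaks included Hspa5 (-2.32 in the authors' deposited table), Ppat, the first enzyme of purine synthesis (-3.68), Gdi2 (-4.13), Wtap (-1.87) and Hspd1, a mitochondrial chaperone (-2.04). In total the authors' deposited table held 5426 differential peaks on 3631 genes, 3055 higher and 2371 lower in L2HGDH cells, with median log2 fold changes of 1.61 (3.05-fold) and -1.68 (3.20-fold). By overlap with the peak lists, 1643 peaks with a positive value were shared with the L2HGDH list alone and 1 with the EV list alone, and 2220 with a negative value were shared with the EV list alone and 0 with the L2HGDH list alone. The first 10% of the gene span held 14.5% (13.3 to 15.8) of higher and 1.39% (0.994 to 1.95) of lower peaks, and at a fold enrichment of at least 4 there were 562 higher and 63 lower peaks. This cut may again not treat both directions alike, as 64.3% of L2HGDH and 49.9% of EV peaks with myxothiazol reached it. On the strongest 25% of the untreated EV list, 82 differential peaks were higher and 557 lower, and on that of the untreated L2HGDH list 1110 and 7.

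The same sites differed in both treatments. Of the 5654 differential peaks of untreated cells, 3732 (66.0%) overlapped one found with myxothiazol. Taking 1 peak pair per gene for 2682 genes, 1946 had a higher and 734 a lower peak in both treatments. This share of 99.9% compares with a mean of 60.2% when signs were permuted among genes (two-sided permutation test, p = 1e-05, the smallest that the 100000 permutations can give). The exceptions were 1 gene higher without and lower with myxothiazol and 1 gene with the opposite pattern.

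Among genes that carried a peak, transcripts of a few pathways had a higher peak in L2HGDH cells more often than others. In untreated cells this held for glycolysis (12 of 13 genes with a peak), nucleotide and aspartate synthesis (12 of 14) and proliferation (13 of 17), against 40.4% of all genes with a peak. The adjusted p was 0.0048, 0.015 and 0.043 (one-sided Fisher's exact test). Examples from the authors' deposited table are Aldoa (3.73-fold higher) and Pkm (2.33-fold) of glycolysis, Uck2 (61.4-fold) and Cad (3.56-fold) of nucleotide synthesis, and Mcm2 (8.75-fold) and Mcm5 (4.44-fold) of the replication helicase. With myxothiazol it held for the integrated stress response (22 of 35, adjusted p = 0.00038), glycolysis (11 of 15, 0.0048) and naive pluripotency (13 of 24, 0.043), against 25.8% of all genes with a peak. The mRNAs of the stress response list were lower in the input of the same cells (20 of 41 fell), which raises peak enrichment by construction. No list was over-represented among genes with a lower peak at an adjusted p under 0.05. The tests treat genes as independent, and with the background limited to expressed genes (mean normalised count of at least 100) 1 of the lists of untreated cells, glycolysis, stayed past the threshold. There the adjusted p was 0.052 for nucleotide and aspartate synthesis and 0.080 for proliferation in untreated cells, and 0.080 for naive pluripotency with myxothiazol.

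Expression tables were taken to rest on the input libraries, and their sign was settled from L2hgdh, so the direction of this gene is no finding. L2hgdh (chromosome 12, 69690436 to 69724874) was 8.86-fold higher in untreated L2HGDH cells (log2 fold change 3.15, standard error 0.11, adjusted p = 2.4e-169 in the authors' deposited table), a value that depends on how far reads of the rat cDNA align to the mouse gene. Mitochondrially encoded mRNAs rose as strongly: mt-Nd2 was 11.1-fold (standard error 0.49 on the log2 scale), mt-Nd1 9.65-fold (0.21) and mt-Co1 8.04-fold (0.35) higher in the authors' deposited table. Cited1, a transcriptional co-activator, rose 9.10-fold, Glrx, a glutaredoxin, 8.64-fold, and Obox6, an oocyte homeobox gene with near-identical copies, 7.34-fold in the authors' deposited table. Rpl39, a ribosomal protein gene with many processed copies in the genome, rose 22.0-fold in the authors' deposited table. Hmgn5 (20.8-fold), Fbl (15.0-fold), Cebpb, a transcription factor of stress and fat cell programmes (9.80-fold), the nuclear RNA Neat1 (8.32-fold), Taf15 (7.30-fold) and Sox21 (6.83-fold) were lower in the authors' deposited table. At an adjusted p of 0.05, 3572 genes were higher and 3627 lower in L2HGDH cells among 17670 genes, of which 1211 and 1130 changed at least by 1 on the log2 scale. The identifiers in the table are gene symbols only.

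Among transcripts for the mitochondrial energy machinery more rose than fell in untreated L2HGDH cells. Of the 7 measured mitochondrially encoded genes, 6 rose and 0 fell (6 adjusted over the list alone), with a median log2 fold change of 2.36 and a list test adjusted p of 0.00018. These genes may vary together beyond the preset correlation of 0.01, which would make this p-value too small. Histone genes, whose mRNAs lack a poly(A) tail, moved the other way, with 9 of 14 lower, 0 higher and a median of -1.30. Of the nuclear complex I genes, 16 rose and 6 fell among 37 (23 adjusted over the list alone, median 0.29, adjusted p = 0.00077), with Ndufb4 6.10-fold and Ndufv2 2.44-fold higher in the authors' deposited table. For complexes IV and V, 17 rose and 3 fell among 27 (20 adjusted over the list alone, median 0.45, adjusted p = 5.7e-09), with Cox5a 3.18-fold and Atp5c1 2.42-fold higher in the authors' deposited table. For complex III, 7 rose and 2 fell among 15 (10 adjusted over the list alone, median 0.27, adjusted p = 0.027). Its Uqcrfs1, the Rieske protein, was 2.07-fold and Uqcrc2 1.95-fold higher in the authors' deposited table. The citric acid cycle had 14 of 24 genes higher and 0 lower (15 adjusted over the list alone, median 0.29, adjusted p = 9.5e-05), with Sdhd 2.38-fold and Pdhb 1.72-fold higher in the authors' deposited table.

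Other groups rose as well. Of 14 genes of hydroxyglutarate metabolism, a list that contains L2hgdh itself, 6 rose and 2 fell (9 adjusted over the list alone, median 0.38, adjusted p = 0.0049), with Mdh1 1.67-fold and Ldha 1.65-fold higher in the authors' deposited table. L2hgdh, which the vector carries, is part of this list test, and no test without it was run. With log2 fold changes as the statistic the adjusted p of the list test was 0.66. Of 19 measured genes of nucleotide and aspartate synthesis, 11 rose and 4 fell (15 adjusted over the list alone, median 0.33, adjusted p = 0.0031), with Prps1 2.61-fold and Asns 2.24-fold higher in the authors' deposited table. Of 15 antioxidant genes, 9 rose and 3 fell (12 adjusted over the list alone, median 0.41, adjusted p = 0.0013), with Nqo1 1.79-fold and Gsta4 1.80-fold higher in the authors' deposited table. Of 76 cytosolic ribosomal protein genes, 38 rose and 15 fell (54 adjusted over the list alone, median 0.39, adjusted p = 9.1e-07), with Rpl18 3.16-fold higher and Rpl36 6.00-fold lower in the authors' deposited table, and copies of these genes elsewhere in the genome make single values uncertain. Of 19 measured genes of the 2-cell-like state, a rare state of embryonic stem cells, 14 rose and 0 fell (15 adjusted over the list alone, median 1.80, adjusted p = 0.0018). Their levels were low: Tmem92 had a mean normalised count of 74.0 and a 5.83-fold rise and Dub1 one of 45.9 and a 4.92-fold rise in the authors' deposited table, and the Dub genes and others of this list have near-identical copies.

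Genes of the neural lineage were lower. Of 12 neuroectoderm genes 0 rose and 6 fell (6 adjusted over the list alone, median -1.06, adjusted p = 0.011), with Nes 2.55-fold, Sox11 5.22-fold and Pax6 5.35-fold lower in the authors' deposited table. Of these 12 genes 6 had a mean normalised count under 10, and at a mean of at least 100 under 5 were left, too few for the test. The 25 naive pluripotency genes went both ways, 11 up and 10 down (22 adjusted over the list alone, median 0.25, adjusted p = 0.18), with Dppa5a 4.14-fold and Dppa2 4.01-fold higher and Sox2 2.40-fold lower in the authors' deposited table. The m6A writers were also divided, 3 up and 3 down of 8 (6 adjusted over the list alone, median -0.06, adjusted p = 0.30), with Zc3h13 3.02-fold and Rbm15 1.78-fold lower and Cbll1 1.92-fold higher in the authors' deposited table. Erasers and readers had 3 up and 6 down of 13 (9 adjusted over the list alone, median -0.30, adjusted p = 0.068), with Hnrnpa2b1 3.16-fold lower and Hnrnpc 1.94-fold higher in the authors' deposited table. Of 39 oxoglutarate-dependent dioxygenases, 7 rose and 15 fell (23 adjusted over the list alone, median -0.19, adjusted p = 0.099), and Phf2 was 2.22-fold lower in the authors' deposited table. The germline genes silenced by DNA methylation had 11 up and 3 down of 22 (14 adjusted over the list alone, median 0.94, adjusted p = 0.12), with Dazl 4.35-fold higher in the authors' deposited table.

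The remaining lists passed no threshold in untreated cells. Proliferation (12 up and 6 down of 25, median 0.30, adjusted p = 0.084), the mitochondrial unfolded protein response (4 and 1 of 12, adjusted p = 0.20) and hypoxia targets (9 and 7 of 26, median 0.08, adjusted p = 0.84) had more members up than down. Hypoxia targets, p53 targets (7 and 6 of 20, median 0.14, adjusted p = 0.76), primitive endoderm (3 and 4 of 15, median 0.23, adjusted p = 0.55), trophectoderm (2 and 2 of 10, median 0.63, adjusted p = 0.88), fibroblasts (2 and 3 of 10, median 0.12, adjusted p = 0.76) and imprinted genes (3 and 7 of 22, median 0.00, adjusted p = 0.47) had a median at or above 0 and a test statistic below 0. The mean was negative for p53 targets, primitive endoderm, fibroblasts and imprinted genes. The formative list (3 and 3 of 15, adjusted p = 0.84) had a median of -0.15, a mean of 0.03 and a test statistic below 0, and the unfolded protein list a median of -0.03, a mean of 0.14 and a statistic above 0. Glycolysis (7 and 7 of 23, adjusted p = 0.81), interferon response (2 and 2 of 19, adjusted p = 0.78) and mesoderm (1 and 2 of 12, adjusted p = 0.84) had statistics above 0. The integrated stress response (6 and 18 of 41, adjusted p = 0.20), cholesterol synthesis (7 and 11 of 24, adjusted p = 0.57) and immediate early genes (1 and 6 of 14, adjusted p = 0.21) had statistics below 0. Adjusted over each list alone, the numbers past the threshold were 18, 6, 17, 13, 8, 4, 6, 10, 8, 15, 4, 3, 24, 19 and 7 in the order proliferation, unfolded protein, hypoxia, p53, primitive endoderm, trophectoderm, fibroblasts, imprinted, formative, glycolysis, interferon, mesoderm, stress response, cholesterol and immediate early. Acta2, an actin of fibroblasts and smooth muscle, was 58.6-fold lower at a mean normalised count of 20.5, and Thy1 3.00-fold higher, in the authors' deposited table.

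Of the 31 lists, 10 rose and 1 fell in untreated cells at an adjusted p under 0.05 over both comparisons. The 10 include hydroxyglutarate metabolism, whose test counts L2hgdh itself. The test presets the correlation between genes at 0.01, and no correlation could be estimated because values per library were not used here. With a preset of 0.05 the adjusted p was 0.055 for neuroectoderm and 0.11 for complex III, and with log2 fold changes in place of the test statistic the calls for mitochondrially encoded, 2-cell-like and neuroectoderm genes were the 3 that held. Complex III also lost its call among genes with a mean normalised count of at least 100 (adjusted p = 0.13) and with a trend over gene span removed (0.085).

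**Figure D2:**
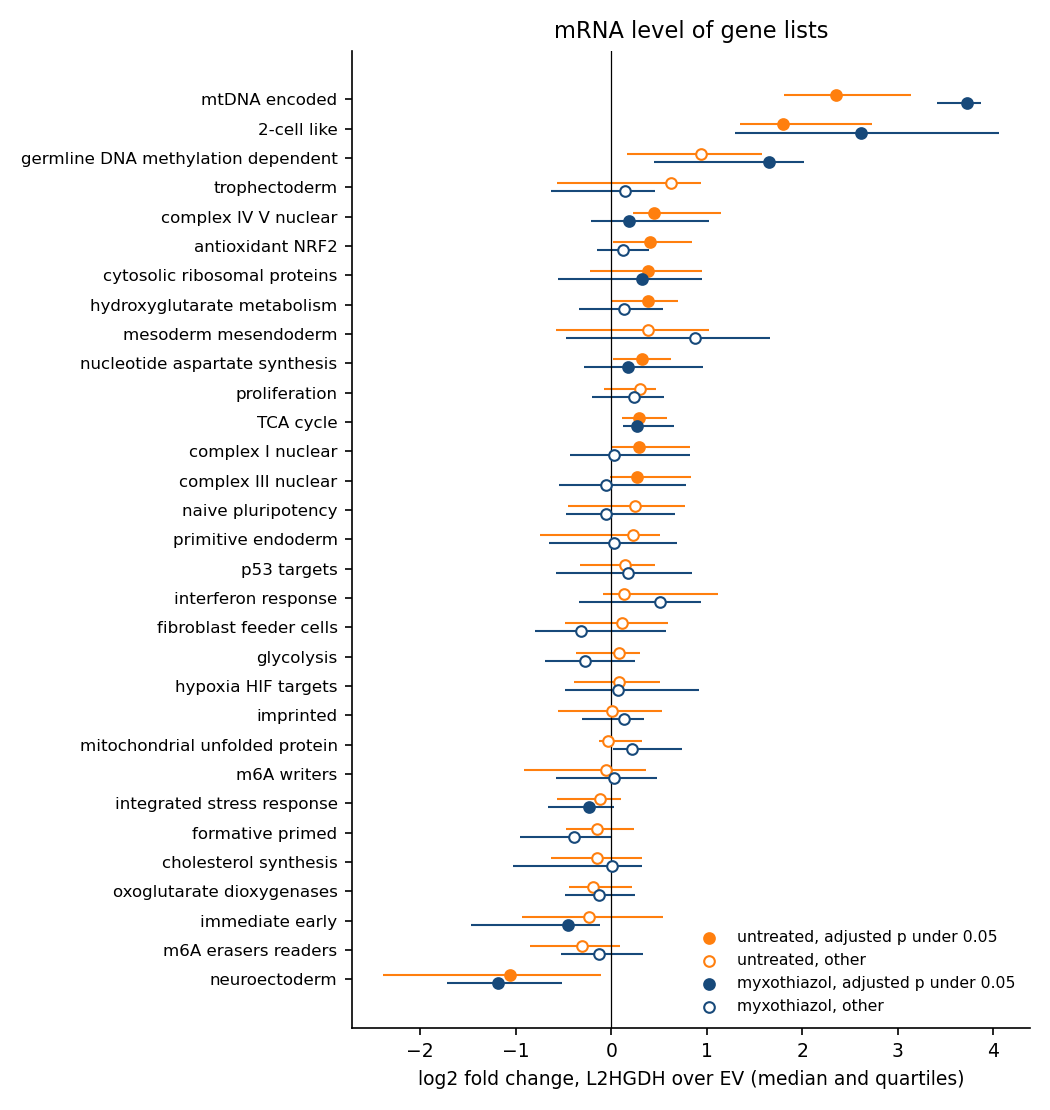
Median log2 fold change (L2HGDH over EV) of the genes of each fixed list, with lines from the lower to the upper quartile, untreated in orange and myxothiazol in blue; filled points have a list test adjusted p under 0.05. Mitochondrially encoded genes have the highest medians, 2.36 untreated and 3.73 with myxothiazol, and neuroectoderm genes the lowest, -1.06 and -1.18.

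With myxothiazol, L2hgdh was 10.7-fold higher in L2HGDH cells (log2 fold change 3.42, standard error 0.13, adjusted p = 1.3e-142 in the authors' deposited table). The mitochondrially encoded mRNAs mt-Nd2 (25.4-fold), mt-Co1 (15.8-fold), mt-Nd1 (13.6-fold) and mt-Cytb (13.2-fold) were again among the strongest rises in the authors' deposited table, with standard errors of 0.11, 0.09, 0.09 and 0.10 on the log2 scale. All 7 measured genes of this group rose (7 adjusted over the list alone, median 3.73, adjusted p = 2.8e-86), while 6 of 10 histone genes fell and 0 rose (median -2.18). The list p-value again rests on the preset correlation of 0.01 and is too small if the mitochondrially encoded genes vary together. Rpl39 was 28.6-fold, Ndufb4 12.7-fold and Med21, a Mediator subunit, 10.9-fold higher in the authors' deposited table. Ccdc85b (27.1-fold), Fbl (17.0-fold), Cebpb (12.5-fold), Ier5l (12.2-fold) and Sox21 (7.99-fold) were lower in the authors' deposited table. In total 3821 genes were higher and 3745 lower among 17523, of which 1811 and 1297 changed at least by 1 on the log2 scale. The median log2 fold change over all genes was 0.09 here and 0.01 in untreated cells.

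Genes of the integrated stress response, which cells switch on when mitochondria fail, were lower in L2HGDH than in EV cells under myxothiazol. Of 41 genes 5 rose and 20 fell (25 adjusted over the list alone, median -0.23, adjusted p = 0.0012). This fall was not shown to be particular to myxothiazol. Untreated cells had 6 up and 18 down, and the list test of the difference between treatments passed no threshold (median difference -0.13, adjusted p = 0.16). Cebpb (12.5-fold), Ddit3 (2.60-fold) and Atf5 (2.72-fold), transcription factors of this response, fell and Asns, which makes asparagine, rose (2.48-fold) in the authors' deposited table. Immediate early genes, which respond to growth signals, had 1 up and 7 down of 14 (8 adjusted over the list alone, median -0.46, adjusted p = 0.035), with Junb 6.16-fold and Jun 3.68-fold lower in the authors' deposited table. Neuroectoderm had 0 up and 5 down of 11 (5 adjusted over the list alone, median -1.18, adjusted p = 0.028), with Sox11 6.03-fold and Nes 2.52-fold lower in the authors' deposited table. Germline genes rose, 10 up and 2 down of 22 (12 adjusted over the list alone, median 1.65, adjusted p = 0.0076), with Hormad1 9.82-fold and Dazl 8.16-fold higher in the authors' deposited table. Genes of the 2-cell-like state had 14 up and 0 down of 19 (15 adjusted over the list alone, median 2.62, adjusted p = 0.027), with Tmem92 4.94-fold and Eif1a 1.94-fold higher in the authors' deposited table.

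Complexes IV and V had 12 up and 5 down of 27 (17 adjusted over the list alone, median 0.19, adjusted p = 0.0016), the citric acid cycle 13 and 3 of 24 (17, median 0.27, 0.0076), ribosomal proteins 36 and 21 of 76 (63, median 0.32, 0.00077) and nucleotide and aspartate synthesis 8 and 6 of 19 (15, median 0.17, 0.024). Cox5a was 3.52-fold, Rps20 5.83-fold and Prps1 3.12-fold higher in the authors' deposited table. Complex I (14 and 14 of 37, adjusted p = 0.34) and complex III (5 and 6 of 15, adjusted p = 0.97) passed no threshold, and the complex III list had a mean of 0.24 with a median of -0.05 and a test statistic below 0. Glycolysis had 6 up and 10 down of 23 (17 adjusted over the list alone, adjusted p = 0.17), with Hk2 1.98-fold lower in the authors' deposited table. The formative list had 0 up and 7 down of 15 (7 adjusted over the list alone, adjusted p = 0.095), the dioxygenases 8 and 17 of 39 (25, 0.062), the antioxidant list 7 and 4 of 15 (11, 0.099) and hydroxyglutarate metabolism 6 and 4 of 14 (10, 0.099). The m6A writers (3 and 3 of 8, adjusted p = 0.76) and the erasers and readers (3 and 6 of 13, adjusted p = 0.18) had the same counts as in untreated cells.

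In all, 7 lists rose and 3 fell with myxothiazol. At a preset correlation of 0.05, complexes IV and V and the mitochondrially encoded genes stayed past the threshold, and the adjusted p was 0.051 for the stress response, 0.069 for germline, citric acid cycle and ribosomal protein genes, 0.092 for neuroectoderm, and 0.11 for the 2-cell-like, nucleotide synthesis and immediate early lists. With the log2 fold change as the statistic the mitochondrially encoded, germline and 2-cell-like lists stayed higher and neuroectoderm lower. The adjusted p was then 0.25 for the stress response, 0.16 for immediate early genes and 0.96 for complexes IV and V, the citric acid cycle, nucleotide synthesis and ribosomal proteins. Among genes with a mean normalised count of at least 100 the adjusted p was 0.20 for germline, 0.062 for nucleotide synthesis and 0.13 for immediate early genes, and the last lost its call with a trend over gene span removed as well (0.085). With that trend removed, complex I (adjusted p = 0.031) and antioxidant genes (0.034) passed the threshold as higher and the dioxygenases (0.02) as lower.

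The L2HGDH effects resembled each other across treatments. Of the genes measured in both tables, 2286 were higher in both (805 would be shared if the calls were independent) and 2490 lower in both (800 if independent), and 179 of the 4955 genes called in both went in opposite directions. Across 9078 genes with a mean normalised count of at least 100 in both tables, Pearson's r of the log2 fold changes was 0.75 and Spearman's rho 0.73. These are correlations across genes, which are not independent replicates, and 77.6% of these genes had the same sign.

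**Figure D3:**
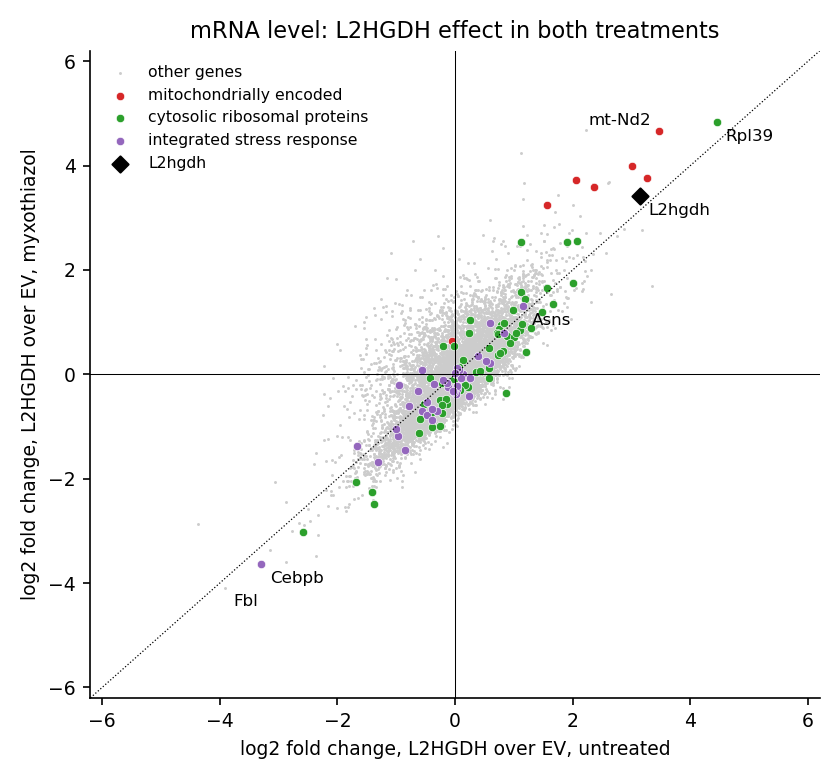
Log2 fold change of mRNA (L2HGDH over EV) in untreated cells against that with myxothiazol for the 9078 genes with a mean normalised count of at least 100 in both, with the mitochondrially encoded, ribosomal protein and integrated stress response lists in colour and a dotted line of equal effects. L2hgdh lies at 3.15 and 3.42, and 77.6% of the genes have the same sign on both axes.

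Some effects differed in size between the treatments. Esf1, a protein of ribosome assembly, and Eif4a2, an RNA helicase of translation initiation, had a higher L2HGDH effect with myxothiazol, by 2.41 (standard error 0.33, adjusted p = 7.6e-09) and 1.83 (0.27, 2.1e-08) on the log2 scale. Dzip3 differed by 2.84 and Cops2 by 2.08 in the same direction. Cd63, a membrane protein of late endosomes, had a lower effect with myxothiazol by -0.92 (0.16, adjusted p = 2.1e-06), Pole4, a DNA polymerase subunit, by -0.997 and the pluripotency factor Tbx3 by -0.62. Of 16950 genes, 1418 had a higher and 1051 a lower effect with myxothiazol, and among 9078 genes with a mean normalised count of at least 100 in both, 1273 had a higher and 1330 a lower one. Among the lists, mitochondrially encoded genes had a larger rise with myxothiazol (median difference 1.19, adjusted p = 0.00086), as did germline genes (0.45, 0.034), and glycolysis (-0.26, 0.0056) and formative genes (-0.31, 0.0073) had a lower effect, as did the nuclear genes of complex I (-0.29, 0.0073), complex III (-0.35, 0.025) and complexes IV and V (-0.28, 0.014). This list test of the difference was chosen after the values had been seen. At a preset correlation of 0.05 the mitochondrially encoded list alone stayed past the threshold (adjusted p = 0.0048). The correlation of the genes of this list was not estimated and may be higher than 0.05.

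The difference went with gene length. Over 5 groups of equal size made from 8979 genes ordered by gene span, its median rose from -0.36 in the shortest to 0.18 in the longest genes, with a Spearman correlation of 0.48 across genes, which are not independent replicates. With this trend removed, 1309 genes had a higher and 478 a lower effect with myxothiazol, and 1330 of the 2442 genes called before stayed called. The adjusted p then was 0.89 for complex I, 0.71 for complex III, 0.89 for complexes IV and V, 0.0079 for glycolysis, 0.029 for formative and 0.028 for germline genes, and 0.0012 for ribosomal protein genes, which had not passed before (0.14) and turned to a higher effect. The mitochondrially encoded genes have no span in the annotation used and were not tested this way.

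**Figure D4:**
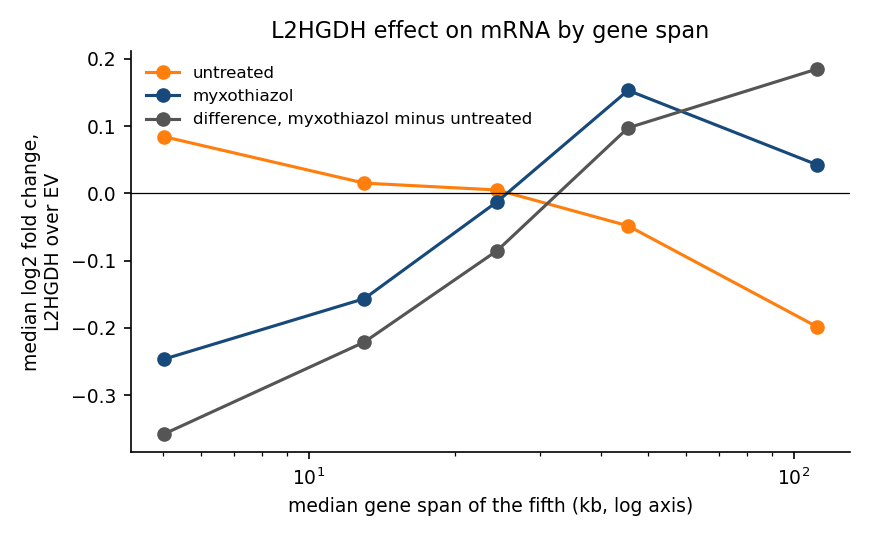
Median log2 fold change (L2HGDH over EV) of genes in 5 groups of equal size by gene span, against the median span of each group in kb on a log axis, for untreated cells, for myxothiazol and for their difference. The difference rises from -0.36 in the group with a median span of 5.02 kb to 0.18 in that of 112 kb.

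Transcripts with a stronger m6A peak in L2HGDH cells were mostly lower in abundance. In untreated cells, Fbl, Sox2 and Zc3h13 had a higher peak and fell 15.0-fold, 2.40-fold and 3.02-fold in the authors' deposited table. Among 2407 genes with only higher peaks, 386 rose and 1242 fell, with a median log2 fold change of -0.30 against -0.07 for 3184 genes with a peak and no differential one (adjusted p = 7.1e-07). The 871 genes with only lower peaks had a median of 0.01, with 238 up and 231 down (adjusted p = 0.01), and the 349 genes with peaks in both directions one of -0.11 (adjusted p = 0.84). With myxothiazol, 129 of 1755 genes with only higher peaks rose and 1299 fell (median -0.63, adjusted p = 6.4e-32), and of 1443 genes with only lower peaks 662 rose and 195 fell (median 0.26, adjusted p = 3.7e-09). The 331 genes with both had a median of -0.21 (adjusted p = 0.02), and 4574 genes with no differential peak had one of 0.00. The input enters both measures, so a lower input raises the fold enrichment of a peak by construction. The adjusted p for lower peaks in untreated cells was 0.28 at a preset correlation of 0.05 and 0.73 against all genes, that for both kinds with myxothiazol 0.28 at the same preset and 0.095 with log2 fold changes, and that for both kinds in untreated cells 0.0078 against all genes.

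**Figure D5:**
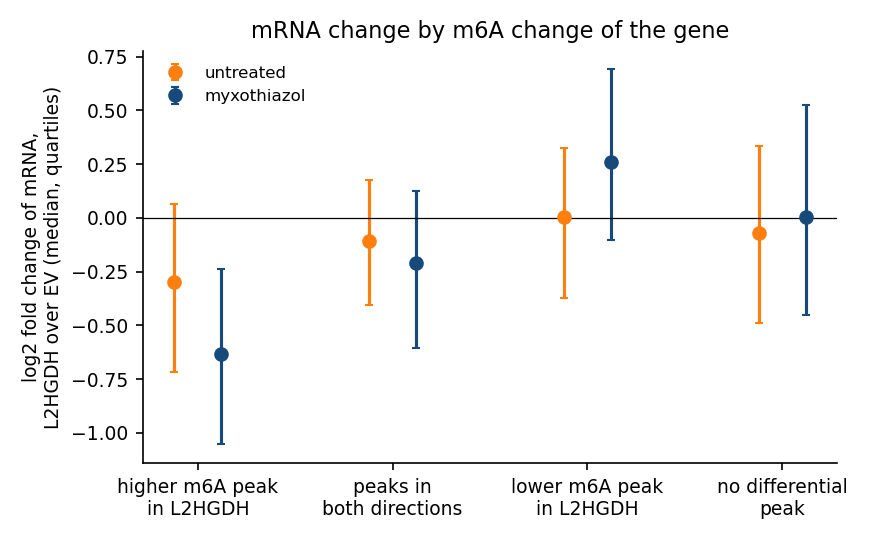
Median log2 fold change of mRNA (L2HGDH over EV), with lines from the lower to the upper quartile, for genes with only higher, both, only lower or no differential m6A peaks, untreated in orange and with myxothiazol in blue. Genes with only higher peaks have the lowest medians, -0.30 and -0.63.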

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

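All tests of explanations in this part except that of a gene length trend over all genes were chosen after the result was seen, and so was the list test of the difference.

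Of 74 genes named for expression, 19 drew a closer look because the L2HGDH effect differed between the treatments in a test of the difference itself, 13 with a higher and 6 with a lower value with myxothiazol. Some of the 74 were named for the smallest adjusted p in this same test, so the number is raised by selection. Over all 16950 genes, 1418 had a higher and 1051 a lower effect. Higher by this log2 difference were Dzip3 (2.84), Esf1 (2.41), Cops2 (2.08), Eif4a2 (1.83), Med21 (1.70), mt-Cytb (1.68), Hmgn5 (1.51), Ndufb4 (1.06), Neat1 (0.99), mt-Co1 (0.98), Eif1a (0.96), Rps20 (0.46) and Taf15 (0.42). Lower were Glrx (-1.59), Pole4 (-0.997), Cd63 (-0.92), Tbx3 (-0.62), Atf5 (-0.59) and Sdhd (-0.36). By the list test of the same difference, mitochondrially encoded genes (median 1.19) and germline genes (0.45) were higher, and complex III (-0.35), formative pluripotency (-0.31), complex I (-0.29), complexes IV and V (-0.28) and glycolysis (-0.26) were lower.

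m6A peaks of L2HGDH and EV cells differed in place and strength. A fall of input reads over the whole gene is excluded as the whole cause, since the median input fall came to at most 33.5% of the median peak rise. A single difference in immunoprecipitation efficiency is excluded only as the whole cause, since it moves the strongest peaks one way. On the strongest 25% of a vector's list, at least 87.2% of the differential peaks were stronger in that vector. The list was taken from the other treatment, which shares no library. These values show shifts in both directions and cannot exclude efficiency as a part of the cause. Median fold enrichment was 6.07 in the untreated L2HGDH list and 2.79 in the untreated EV list. With myxothiazol these medians were 5.35 and 3.99. Recovery of gene starts that differs between the libraries stays open, since among differential peaks in the lists of both vectors the share in the first 10% of the gene span was at least 3.47 percentage points higher for higher than for lower peaks, with overlapping 95% intervals. An effect of L2HGDH on m6A itself stays open beside it, and base composition was not analysed here.

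Mitochondrially encoded mRNAs were higher in L2HGDH cells. Weaker poly(A) selection in L2HGDH libraries would raise histone mRNAs, whose median log2 fold change was -1.30 in untreated cells and lower with myxothiazol. This argues against it only if the cells of both vectors made the same amount of histone mRNA, which was not measured. A real fall of histone mRNA could hide weaker selection. Low counts are excluded, with a median mean normalised count of 9262 in the lower of the 2 tables. An effect of L2HGDH on mitochondrial transcripts and other differences between the libraries stay open, as neither was tested, and copies of mitochondrial sequence in the nuclear genome were not analysed here.

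The L2HGDH effect on expression differed between myxothiazol and untreated cells. A gene length trend is excluded as the whole cause, since 73.2% as many genes were called after the trend was removed, although only 54.5% of the genes called before stayed called and the later calls include new genes. For the 3 lists of nuclear respiratory chain genes the trend has the values it needs, the lowest adjusted p without it being 0.71. Low counts are excluded, with 86.8% of called genes at a mean of at least 100 in both tables. An effect of respiratory inhibition on what L2HGDH does was not separated from library differences between the treatments.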

How the results depend on the processing

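The list test of the difference and removal of the trend over gene span before list tests were chosen after the result was seen; removal of that trend from the difference over all genes was added after the files had been seen, with its bound set before its own result.

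No paired analysis was possible because the values describe comparisons of groups and none belongs to a single library. For the same reason edgeR against DESeq2, leaving out each replicate, replicate number as a block, no low count filter and other splits of the samples were not run, and depth per library, which limits peak calling and low counts, is unknown. Position in transcripts with its stop codon window and motif was not run because no transcript annotation or genome sequence was used here. A differential FDR of at most 0.01 and adjustment over all genes with a p-value changed nothing by construction. For 265 named gene results, 1204 of 1298 values kept their direction and call and 94 lost the call, with 0 reversed. For the lists 312 of 359 values stayed, 38 lost and 7 gained the call and 2 reversed.

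At a fold enrichment of at least 4 the lists held 1551 (EV untreated), 8007 (EV myxothiazol) and 5305 peaks (L2HGDH myxothiazol), and counted as genes 5404, 4997 (L2HGDH untreated), 7325 and 4733, lower by construction. The untreated ratio of L2HGDH to EV peaks turned to 1.09 at fold 2, 3.87 at fold 4 and 1.01 at an FDR of 1e-05, and was 0.925 for genes; the cause was not tested. With myxothiazol it was 0.532, 0.663 and 0.646 at fold 2, fold 4 and for genes. The EV ratio of myxothiazol to untreated was 1.88, 5.16, 1.77 and 1.36 at fold 2, fold 4, the stricter FDR and for genes, and the L2HGDH ratio 0.883 at fold 4; the cause was not tested.

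Overlaps are given in the order L2HGDH with EV untreated, EV untreated with EV myxothiazol, L2HGDH myxothiazol with EV untreated, L2HGDH untreated with EV myxothiazol, L2HGDH myxothiazol with untreated, and L2HGDH with EV myxothiazol. With 50% of the shorter peak they were 39.8, 85.0, 40.7, 44.8, 84.1 and 45.1%, and with 50% of both peaks 24.8, 59.7, 25.6, 23.8, 74.96 and 24.0%, lower by construction. At fold 4 they were 3.66, 66.4, 4.11, 11.7, 83.3 and 12.6%, and for genes 68.1, 93.9, 68.2, 79.2, 89.7 and 79.1%; the cause was not tested.

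Differential peaks numbered 2727 higher (untreated) and 1552 lower (myxothiazol) at 1 per gene, and at fold 4 1529 higher and 40 lower untreated, 562 and 63 with myxothiazol, fewer by construction. The cut at fold 4 may not treat both directions alike, since the range of fold enrichment differs between the lists of the vectors. With expressed genes as background 1 list was over-represented in untreated cells; the cause was not tested. A log2 fold change of at least 1 left 1211 higher and 1130 lower genes untreated, 1811 and 1297 with myxothiazol, and an adjusted p of 0.01 left 817 higher and 403 lower effects, fewer by construction; without the span trend 478 were lower.

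The lists past the threshold were 0 lower (untreated), 2 higher and 0 lower (myxothiazol) at a preset correlation of 0.05, 3 lower (untreated) at 0, and 2 higher (untreated), 3 higher and 1 lower (myxothiazol) with log2 fold changes; the cause was not tested. At a mean of at least 100 they were 0 lower (untreated), 4 higher and 1 lower (myxothiazol), in part by construction, since neuroectoderm and the 2-cell-like list kept under 5 genes and were not tested. Without the span trend the difference turned for complexes IV and V (adjusted p = 0.89) and ribosomal proteins (0.0012). For expression of genes with lower peaks, untreated, the adjusted p was 0.28 at a preset of 0.05 and 0.73 against all genes; for genes with both kinds it was 0.0078 against all genes untreated, and 0.28 at a preset of 0.05 and 0.095 with log2 fold changes under myxothiazol; the cause was not tested.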

Other observations

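Levels in the myxothiazol and the untreated expression table were set side by side after the result was seen, as a description with no test, because the tables were normalised separately. Only genes with a geometric mean of at least 10 over the mean normalised counts of both were kept. Each ratio was centred on the median of these genes, and list members below this level are not counted.

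Genes of the integrated stress response stood higher in the myxothiazol table, in mean normalised counts that pool EV and L2HGDH cells. Of 41 genes 40 were higher, with a median ratio of 1.88-fold. Ddit3 was 5.34-fold, Cebpb 5.21-fold, Aldh1l2, a mitochondrial folate enzyme, 3.56-fold, Gdf15, a secreted stress hormone, 3.24-fold, Atf5 3.13-fold and Trib3 3.02-fold higher between the authors' deposited tables. Cholesterol synthesis genes were higher for 23 of 24 (median 1.34-fold), with Pcsk9, which lowers the LDL receptor, 3.99-fold and Lss 2.06-fold higher between the authors' deposited tables. Of 12 primitive endoderm genes 10 were higher, with Lama1, a laminin chain, 2.65-fold higher between the authors' deposited tables, and of 19 p53 targets 14. Of other lists of cell types, 6 of 6 trophectoderm, 5 of 7 fibroblast, 3 of 6 neuroectoderm, 5 of 14 formative and 12 of 25 naive pluripotency genes were higher. Genes of the 2-cell-like state were higher for 1 and lower for 12 of 13, with a median ratio 1.61-fold lower.

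Proliferation genes stood lower in the myxothiazol table, 23 of 25 (median 1.42-fold), with Ccne1, a cyclin of the start of S phase, 2.13-fold and Cdk1 1.77-fold lower between the authors' deposited tables. Hypoxia targets were lower for 16 of 24, with a median log2 ratio of -0.41. Mitochondrially encoded genes were lower for 7 of 7, with a median log2 ratio of -0.38, although their L2HGDH effect was larger with myxothiazol. Untreated means pool 3 EV and 4 L2HGDH inputs and those with myxothiazol 4 and 4, which by itself lowers the ratio of genes that are higher in L2HGDH cells and raises that of genes that are lower.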
